A study of Homo sapiens with 6 samples.

How the data were processed

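Gene expression was measured by 3' end RNA sequencing in Karpas-422, a B cell non-Hodgkin lymphoma line. Per the labels' protocols, wild-type cells were kept for 10 days with 5 µM SETD2-IN-1, an inhibitor of the H3K36 methyltransferase SETD2, or with 0.1% v/v DMSO as vehicle. The 6 libraries form 2 groups of 3. Per the labels' protocols, RNA was isolated with a column kit and libraries were made from polyadenylated RNA with the forward version of the QuantSeq 3' kit, in which each read comes from the 3' end of a transcript and gene length has little influence on the count. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

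The deposited file is a single table of the authors' comparison of both groups, with no values per library. The submitters' processing notes name STAR 2.7.0e, HTSeq 0.6.1 and DESeq2, and the builds GRCh38 and hg38, without their order or settings. The column names, per the file headers, are those of DESeq2 as used by the submitters. The mean level of each gene is the authors' mean of normalized counts over the libraries, a signal on a count scale. The log2 fold change and its standard error are the authors' deposited values on the log2 scale. The deposited Wald statistic is a score equal to the fold change over its standard error, with a largest relative difference of 2.73% among statistics above 0.5 in size. The deposited p-value follows from that statistic as a 2-sided normal p, with a largest difference of 0.0018 in log10. Recomputing the Benjamini-Hochberg adjustment over all 11423 rows gave the authors' adjusted p-value to within 0.785%. The table therefore holds the genes that were adjusted, and their lowest mean level is 16.5. One row repeats another exactly and was removed, which left 11422 genes.

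The header does not name the direction of the contrast. Positive fold changes were read as higher with SETD2-IN-1 than with DMSO, since the deposited table is named for the inhibitor. No value in the table settles this reading, and if the authors coded the opposite contrast every direction given here is inverted, while sizes, errors and p-values stay as they are. The deposited fold changes are shrunken toward 0 as far as the values show. Their standard error reaches a ceiling of 0.165 at a mean level of about 49.5 and falls again below it, with a median of 0.164 at levels of 40 to 60, 0.147 under 20 and 0.0771 over 1000. A normal prior centred on 0 gives such a ceiling. Inverting that relation gives a median factor of 1.06 between unshrunken and deposited fold changes at levels over 1000, and of 2.01 at levels of 40 to 60. On this inference, deposited folds of low genes are understated in general. Unshrunken folds of genes chosen for their size tend in turn to be too large. The depth per library is unknown, because no total is given. The mean levels sum to 12842024 normalized counts over the listed genes, of which the 10 highest genes hold 8.67%.

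Gene names came from a table of Ensembl identifiers, which held 11418 of the 11422 genes, and positions and gene types from GENCODE 29 on GRCh38, which held 11356. The annotation used by the authors for counting, and whether counting used the strand, are not given in the sources used here.

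A gene was called changed when the authors' adjusted p was under 0.05, a rule fixed for a table of this kind. Because there are no counts, no count model was fitted. The gene lists were 33 lists of pathways, complexes and cell type markers, of which 29 had at least 5 measured members. They were tested with cameraPR (limma 3.58.1, R 4.3.3) on the authors' statistic with a preset inter-gene correlation of 0.01, adjusted over the 29 lists (Benjamini-Hochberg). An estimated correlation and fry need values per library and were not available to this test. The method was tried on simulated statistics for the 11422 genes of this comparison, with 6 lists shifted by 2 units in each of 50 draws. There cameraPR recovered 93.7% of the shifted lists and called 0.4% of the lists that shared no member with them. The simulated statistics were normal and independent between genes. These rates therefore do not cover lists of co-regulated genes or lists led by an extreme member. Genes are named by a fixed rule: among called genes with a symbol other than a clone or LINC name and a mean level of at least 20, the 12 largest folds in each direction; the 6 smallest p-values at levels of at least 200; SETD2; and up to 4 called members of each list. The part of the rule that asks for separation of the libraries could not be applied. One gene that the rule gives is not reported here. Members of lists that are named without having passed were chosen after their values were seen, as were GLIPR1, ZFHX2, CD27 and POU2AF1. The threshold, the lists, their test and this rule were set before the data were examined. Further computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

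Alternatives were a minimum mean level of 50, adjusted p thresholds of 0.01 and 0.1, a minimum fold, a preset correlation of 0.05, and lists without their strongest member. Centring on the summed level, undoing the shrinkage and testing ranks were added after the data were seen. A replicate block, other normalizations or tools, other pseudocounts, a looser filter, leaving out libraries and regrouping them all need values per library and were not run.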

Results

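Transcript levels were compared between Karpas-422 cells, a lymphoma line of germinal centre B cell type, kept for 10 days with 5 µM of the SETD2 inhibitor SETD2-IN-1 and cells kept with 0.1% DMSO, with 3 libraries per group. The comparison asks how transcript levels differ when cells are kept with an inhibitor of SETD2, the enzyme that trimethylates lysine 36 of histone H3 over transcribed genes. The data used here hold no measure of H3K36 methylation, so effects of the compound apart from SETD2 cannot be told apart. All levels, log2 fold changes, standard errors (SE) and adjusted p-values of single genes given here are values of the authors' deposited table, whose columns, per the file headers and the submitters' processing notes, are those of DESeq2's Wald test by the authors, with adjusted p-values that follow the Benjamini-Hochberg method. That table holds 11422 genes with mean normalized counts from 16.5 to 284308 and a median of 310.1, and no values per library, so that neither the depth of a library nor the spread among replicates is known other than through the SE. Positive values are read as higher with the inhibitor, which the table's header does not state. The words rose and fell below rest on that reading.

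SETD2 itself (ENSG00000181555, chromosome 3, 47016429 to 47163967, minus strand, GRCh38) had a mean level of 2148 normalized counts in the authors' deposited table. Its log2 fold change was -0.24 (SE 0.093), which did not pass the threshold of 0.05 on the authors' adjusted p (adjusted p = 0.091). The inhibitor acts on the enzyme, so this transcript does not check the labels.

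At an adjusted p under 0.05 in the authors' deposited table, 1043 genes, 9.13% of those listed, were called. Of these, 505 rose and 538 fell. Changes were small for the most part. The median log2 fold change was 0.34 among the genes that rose and -0.40 among those that fell, and 14 genes reached a change of 1 or more on the log2 scale, of which 5 rose and 9 fell. As far as their SEs show, the table's fold changes are shrunken toward 0, by a factor of about 2.01 for genes near 50 normalized counts. With this inferred shrinkage undone, 87 called genes reached a log2 change of 1, of which 40 rose and 47 fell. Unshrunken values of genes chosen for their size tend to be too large, so this count does not replace the 14.

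**Figure D1:**
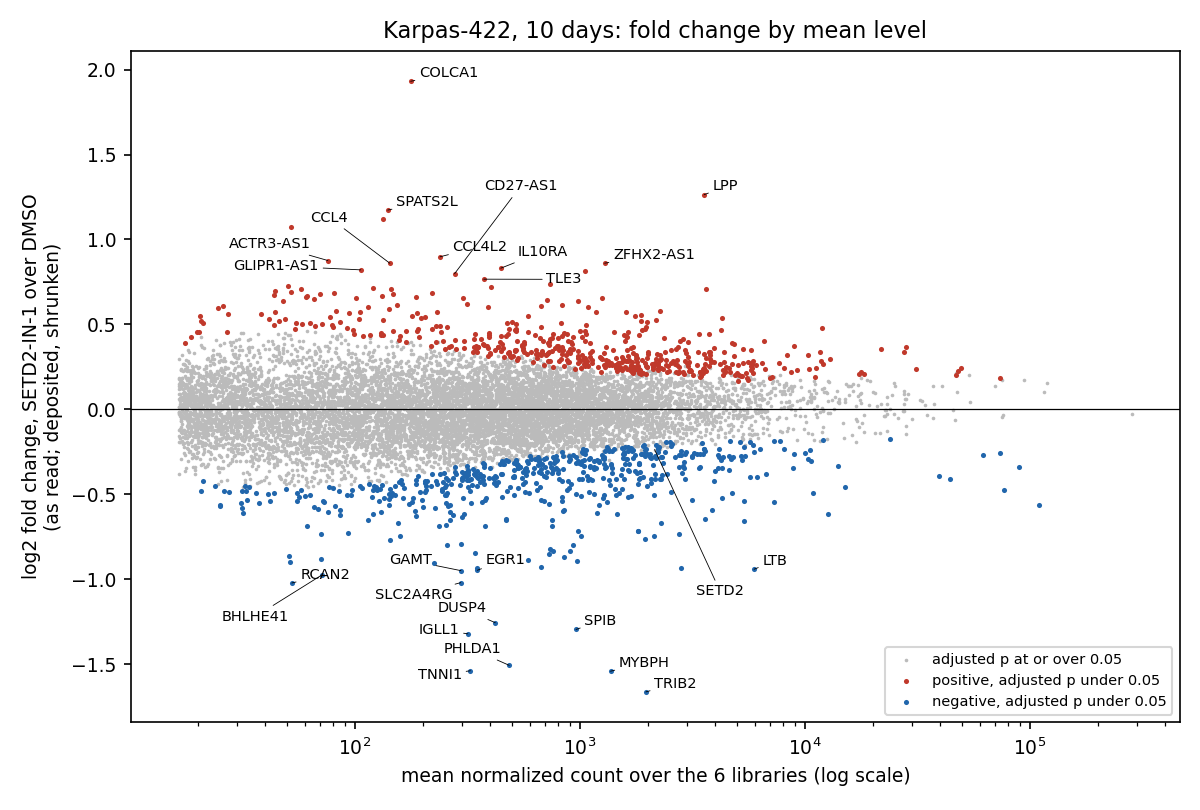
Log2 fold change of each gene (vertical axis, shrunken values of the authors' deposited table, positive read as higher with SETD2-IN-1) against its mean normalized count over the 6 libraries (horizontal log axis). Red and blue points are the 505 positive and 538 negative genes with an adjusted p under 0.05, grey points the rest, and labels mark SETD2 and the genes named in the text for the size of their change or the smallest p.

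By the shrunken fold changes, the 12 largest falls among genes with a symbol other than a clone or LINC name were led by TRIB2, a Tribbles pseudokinase, and MYBPH, which encodes myosin binding protein H. TRIB2 (ENSG00000071575, chromosome 2, 12716889 to 12742734) fell by 1.66 on the log2 scale (SE 0.081), which is 3.17-fold, with an adjusted p of 3.67e-90 in the authors' deposited table (Wald test). MYBPH (chromosome 1, 203167811 to 203175813) fell by 1.54 (SE 0.081, adjusted p = 4.15e-77). TNNI1, a troponin I gene of slow skeletal muscle, fell 2.90-fold and PHLDA1, which encodes a pleckstrin homology-like domain protein, 2.84-fold. In the authors' deposited table IGLL1, a component of the surrogate light chain of the pre-B cell receptor, fell by 1.32 on the log2 scale (SE 0.12), SPIB, an Ets family transcription factor of B cells, fell 2.45-fold, and DUSP4, a phosphatase of MAP kinases, fell 2.39-fold. The remaining genes of this group were RCAN2, a regulator of calcineurin, with a 2.03-fold fall, SLC2A4RG (2.03-fold), the transcriptional repressor BHLHE41 (log2 fold change -0.97), the creatine synthesis gene GAMT (1.93-fold) and the immediate early gene EGR1 (1.93-fold). With the shrinkage undone the order differed, with RCAN2 at -1.94 (SE 0.31), TNNI1 at -1.83 (SE 0.14) and TRIB2 at -1.78 (SE 0.086). LTB, the gene of lymphotoxin beta, had one of the 6 smallest p-values, with a fall of 0.94 on the log2 scale (SE 0.070, adjusted p = 1.79e-37).

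COLCA1 showed the highest rise among the called genes of the authors' deposited table. This transcript (ENSG00000196167, chromosome 11, 111290787 to 111305045, minus strand, annotated as antisense) rose by a log2 fold change of 1.93 (SE 0.14), which is 3.81-fold, at a mean level of 177 normalized counts, with an adjusted p of 9.79e-36 in the authors' deposited table (Wald test). LPP, which encodes a LIM domain protein of focal adhesions (chromosome 3, 188153284 to 188890671), rose 2.40-fold at a mean level of 3569 (log2 fold change 1.26, SE 0.075, adjusted p = 7.11e-61). SPATS2L rose 2.25-fold. The chemokine genes CCL4L2 and CCL4 rose 1.86-fold and 1.81-fold, and since they are near-identical copies the division of reads between them is uncertain. With the shrinkage undone COLCA1 stood at 2.60 (SE 0.19) on the log2 scale, SPATS2L at 1.63 (SE 0.21) and ACTR3-AS1 at 1.55 (SE 0.29), ahead of LPP at 1.34 (SE 0.079). IL10RA, a receptor subunit for interleukin 10, rose 1.78-fold and the corepressor gene TLE3 1.70-fold. A further 4 of the 12 largest rises among genes so named in the authors' deposited table were non-coding: ACTR3-AS1 (1.84-fold), ZFHX2-AS1 (1.82-fold), GLIPR1-AS1 (1.77-fold) and CD27-AS1 (1.74-fold). With COLCA1, 5 of the 12 largest rises were non-coding, against 0 of the 12 largest falls. Genes with clone or LINC names were left out of both counts. Over all listed genes, 5.89% of long non-coding genes were called, against 9.79% of coding genes, shares that were not matched on mean level. Whether the authors' counting used strand is not given in the sources used here, so that reads of these transcripts and of the genes they overlap may not be fully separated. Of the genes that the named transcripts overlap on the other strand, GLIPR1 rose by 0.46 (SE 0.10), while ZFHX2 at 0.36 (SE 0.16) and CD27 at 0.20 (SE 0.10) did not pass, and POU2AF1, upstream of COLCA1 on the same strand, was at 0.02 (SE 0.062).

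Of the 29 gene lists tested, 7 stood apart from the other genes at an adjusted p under 0.05 (cameraPR on the authors' statistic, preset correlation of 0.01), 5 toward lower and 2 toward higher expression. No correlation between genes could be estimated from a table without libraries, so that these p-values rest on the preset one. The G2/M call held under each alternative tried, and each of the other 6 calls ended under at least 1 of them. There the highest adjusted p was 0.325 for mitochondrially encoded and for immediate early genes. It was 0.436 for pan-B cell and unfolded protein response genes, 0.551 for germinal centre genes and 0.632 for MYC targets. The mitochondrially encoded call ended only with unshrunken fold changes in place of the statistic. Under the other alternatives its adjusted p was 0.0127 or lower (cameraPR).

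Genes of mitosis fell together. Of 32 measured G2/M genes, 24 fell, 0 rose and 8 did not pass, and adjusted over the list alone 27 fell and 1 rose. At an unadjusted p under 0.05, 28 fell and 1 rose. The list's median log2 fold change was -0.43 (adjusted p = 2.64e-37, cameraPR). CCNB1, the gene of cyclin B1, fell by 0.93 on the log2 scale (SE 0.099) in the authors' deposited table, UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, by 0.80 (SE 0.082), PTTG1, which encodes securin, by 0.73 (SE 0.078), and the mitotic kinase gene AURKB by 0.67 (SE 0.073). Among the members that did not pass, CCNA2 was at 0.19 (SE 0.091, adjusted p = 0.205) and MKI67 at -0.16 (SE 0.077, adjusted p = 0.198). Genes of the G1/S transition and DNA replication gave another picture. Of 31 measured G1/S genes 2 rose, 0 fell and 29 did not pass, with a list median of 0.060 (adjusted p = 0.337, cameraPR), adjusted over the list alone 2 rose and 1 fell, and at an unadjusted p under 0.05 5 rose and 2 fell. The genes that rose were UNG, a uracil DNA glycosylase (log2 fold change 0.44, SE 0.094), and SLBP, the histone stem-loop binding protein (0.28, SE 0.085). The medians of the G1/S and G2/M lists differed by 0.49, and 100000 permutations of list membership gave the smallest p they can give, 1e-05 (2-sided), although genes are not independent replicates.

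**Figure D2:**
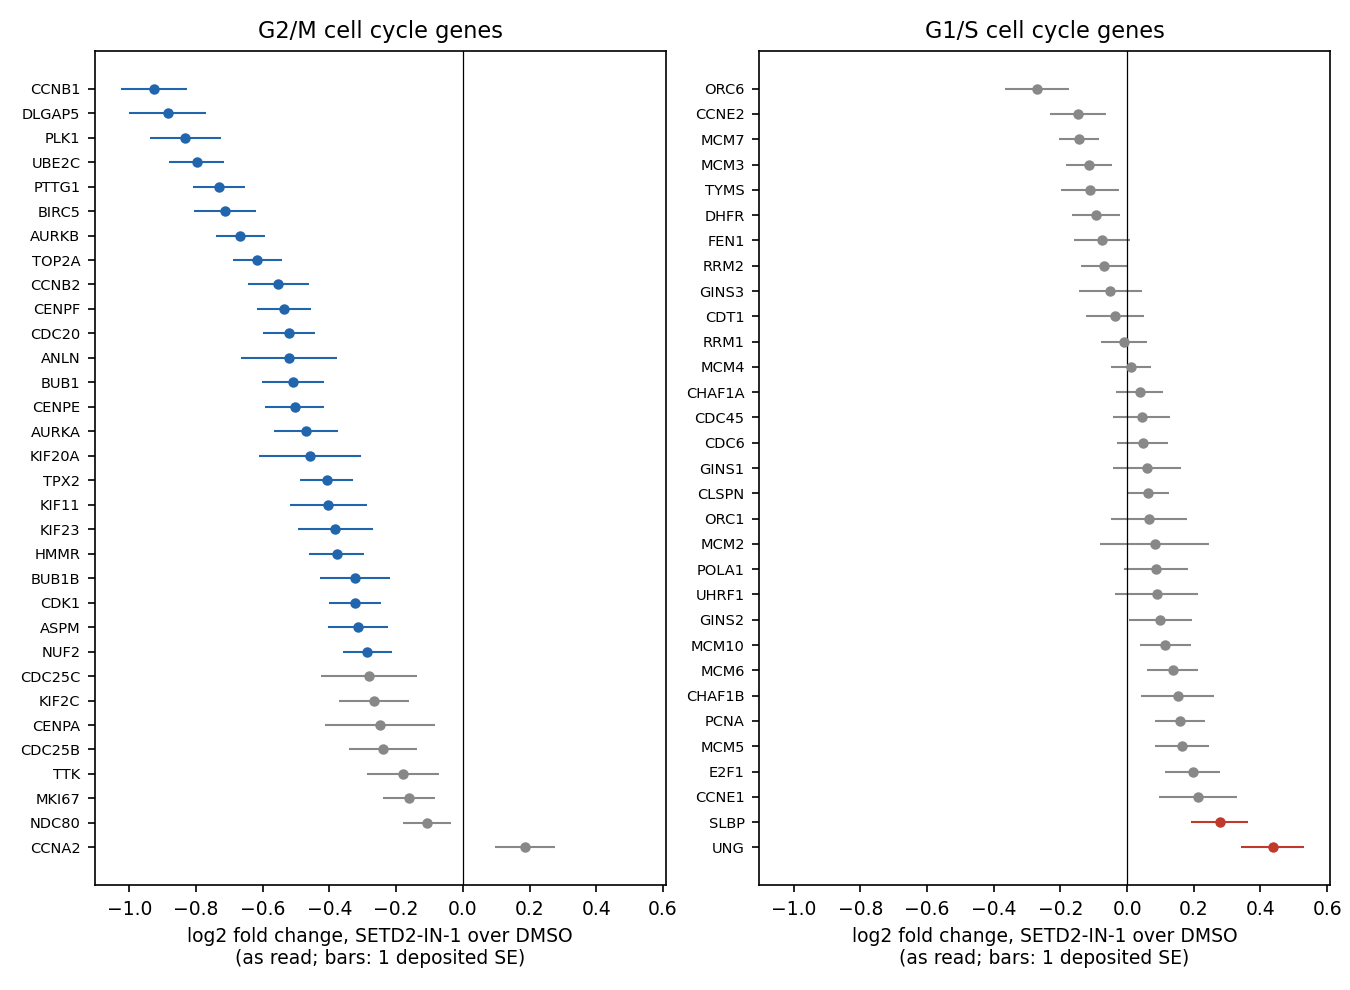
Log2 fold changes of the authors' deposited table (horizontal axis, positive read as higher with SETD2-IN-1) for the measured G2/M genes (left) and G1/S genes (right), 1 gene per row, with bars of 1 deposited SE. Blue and red mark genes with an adjusted p under 0.05. In the G2/M list 24 of 32 genes are blue, and in the G1/S list 2 of 31 are red and none is blue.

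Among the genes encoded by the mitochondrial chromosome, 6 of 15 fell, 0 rose and 9 did not pass, with a list median of -0.15 (adjusted p = 5.71e-07, cameraPR), and 9 fell and 0 rose both adjusted over the list alone and at an unadjusted p under 0.05. MT-CO3 fell by 0.56 on the log2 scale (SE 0.058, adjusted p = 2.42e-19 in the authors' deposited table), MT-ATP6 by 0.47 (SE 0.082), MT-CYB by 0.41 (SE 0.082) and MT-CO2 by 0.34 (SE 0.056). The ribosomal RNA MT-RNR2, the most abundant transcript of the table, was at -0.03 (SE 0.078) and MT-ND1 at 0.11 (SE 0.15). The nuclear genes of oxidative phosphorylation did not stand apart from other genes. Of 29 measured, 2 rose, 5 fell and 22 did not pass (median 0.082, adjusted p = 0.472, cameraPR), and 2 rose and 6 fell adjusted over the list alone, NDUFA2 rising by 0.34 (SE 0.065) and NDUFB9 falling by 0.28 (SE 0.067).

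**Figure D3:**
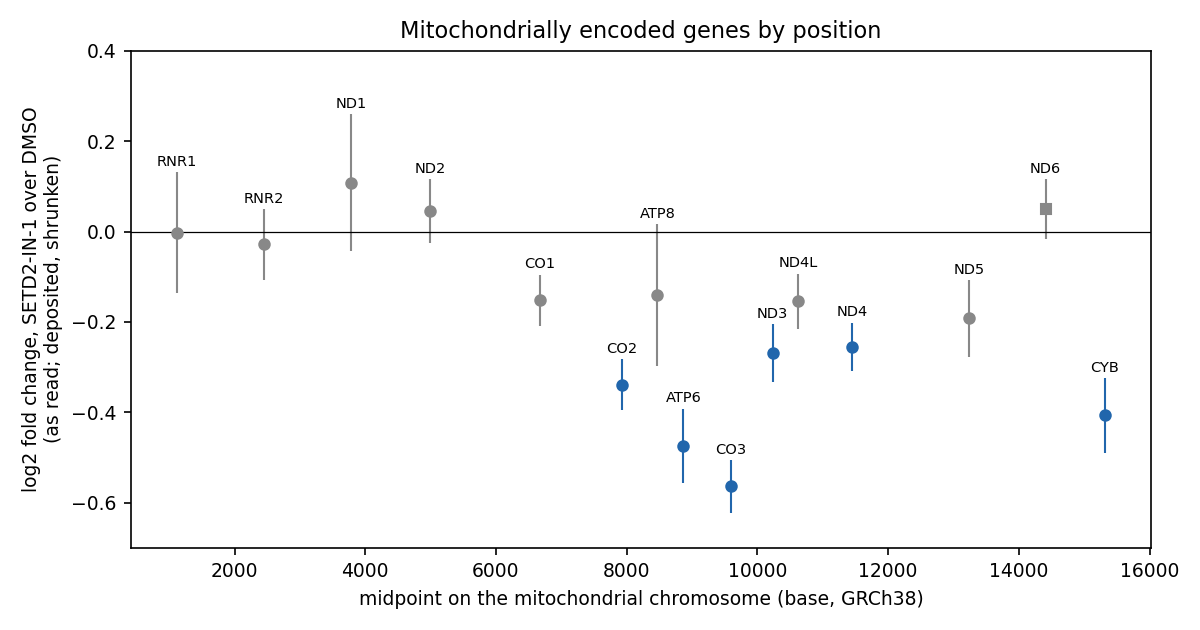
Log2 fold changes of the 15 mitochondrially encoded genes (vertical axis, authors' deposited table, bars of 1 deposited SE) by the midpoint of the gene on the mitochondrial chromosome (horizontal axis, GRCh38). Blue marks the 6 genes with an adjusted p under 0.05, and the square marks MT-ND6, the gene on the other strand. The 4 genes on the left, from RNR1 to ND2, lie between -0.03 and 0.11, and CO3 is lowest at -0.56.

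Genes of B cell identity moved, in both directions. Of 20 measured genes of the B cell receptor and pan-B cell list, 7 fell, 2 rose and 11 did not pass (median -0.093, adjusted p = 0.00117, cameraPR). Adjusted over the list alone, 7 fell and 3 rose. CD24 fell by 0.93 on the log2 scale (SE 0.076), CD22, an inhibitory coreceptor, by 0.71 (SE 0.088), PAX5, a transcription factor of B cell identity, by 0.34 (SE 0.055) and VPREB3 by 0.34 (SE 0.066) in the authors' deposited table. Of 22 measured germinal centre genes, 5 fell, 1 rose and 16 did not pass (median -0.01, adjusted p = 0.00442, cameraPR), with 5 falling and 2 rising adjusted over the list alone. SPIB is the strongest member. MYBL1, which encodes A-Myb, fell by 0.72 (SE 0.080), IRAG2 by 0.65 (SE 0.078) and BCL6, a transcriptional repressor of the germinal centre, by 0.35 (SE 0.059). Both calls rest on their strongest member: without SPIB the germinal centre list had an adjusted p of 0.167, and without CD24 the pan-B cell list had one of 0.0773. Of the 11 measured plasma cell genes 0 rose and 0 fell at an adjusted p under 0.05 (median -0.045, adjusted p = 0.784, cameraPR), and 0 passed adjusted over the list alone, with 1 positive and 2 negative at an unadjusted p under 0.05. XBP1 and SDC1 were at -0.11 and -0.06.

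Immediate early genes, transcription factors induced by signalling, fell in 3 of 12 cases, with 0 that rose and 9 that did not pass (median -0.15, adjusted p = 0.00974, cameraPR), and 4 fell adjusted over the list alone. These were EGR1, with a fall of 0.95 on the log2 scale (SE 0.12), KLF6, with 0.54 (SE 0.14), and JUND, with 0.42 (SE 0.086) in the authors' deposited table. Without EGR1 the list's adjusted p was 0.167. Genes of the unfolded protein response rose in 5 of 19 cases, and 0 fell (median 0.039, adjusted p = 0.00774, cameraPR). Adjusted over the list alone, 6 rose. HSPA5, the endoplasmic reticulum chaperone BiP, rose by a log2 fold change of 0.48 (SE 0.059), CRELD2 by 0.34 (SE 0.090), SDF2L1 by 0.29 (SE 0.078) and DNAJB11 by 0.28 (SE 0.072). Without HSPA5 the list's adjusted p was 0.111. In the list of MYC targets and ribosome biogenesis 4 of 29 genes rose, 1 fell and 24 did not pass (median 0.11, adjusted p = 0.0383, cameraPR), with 8 rising and 1 falling adjusted over the list alone. NCL, which encodes nucleolin, rose by 0.24 (SE 0.060), FBL, fibrillarin, by 0.24 (SE 0.064) and NPM1, nucleophosmin, by 0.21 (SE 0.054), and ODC1, ornithine decarboxylase, fell by 0.36 (SE 0.078) in the authors' deposited table. MYC was at -0.14. This call ended when genes under 50 normalized counts were left out (adjusted p = 0.0527).

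The enzymes and readers of H3K36 methylation did not stand apart as a list. Of 27 measured, 1 rose, 2 fell and 24 did not pass (median -0.08, adjusted p = 0.201, cameraPR), and the counts adjusted over the list alone were the same. The demethylase gene KDM4B fell by 0.34 on the log2 scale (SE 0.083) and MORF4L1, which encodes a reader of H3K36 methylation, by 0.24 (SE 0.069), and BRPF1 rose by 0.32 (SE 0.092) in the authors' deposited table. Of 24 measured Polycomb genes 3 fell and 0 rose (adjusted p = 0.337, cameraPR), also adjusted over the list alone. RYBP fell by 0.55 (SE 0.13), CBX2 by 0.47 (SE 0.15) and SUZ12, a core subunit of PRC2, by 0.28 (SE 0.081). EZH2 was at 0.02 (SE 0.063).

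Several lists held called genes in both directions without a shift of the list. Type I interferon response genes rose in 7 and fell in 3 of 32 cases (adjusted p = 0.134, cameraPR), and in 11 and 6 adjusted over the list alone. RSAD2, which encodes viperin, rose 1.63-fold and IFIT2 1.52-fold, with IFI44L at 1.28-fold, while LGALS3BP fell by 0.54 on the log2 scale (SE 0.095). NF-kB target genes rose in 3 and fell in 3 of 17 cases (adjusted p = 0.784, cameraPR), the same counts as adjusted over the list alone. There CFLAR, which encodes the caspase-8 regulator c-FLIP, rose by 0.66 (SE 0.079) and CCL4 rose, and LTB and TNF fell, TNF by 0.41 (SE 0.075). The list's median was 0.05 and its mean 0.046, while its test pointed to lower values. Integrated stress response genes rose in 4 and fell in 3 of 22 cases (adjusted p = 0.357), and in 6 and 3 adjusted over the list alone. CHAC1 rose 1.64-fold at a mean level of 57.6, SLC7A5 by 0.35 (SE 0.085) and SLC3A2 by 0.29 (SE 0.072), and MTHFD2 fell by 0.24 (SE 0.061). In the BCL2 family 3 of 12 genes rose and 1 fell (adjusted p = 0.519), also over the list alone. BCL2, an inhibitor of apoptosis, fell by 0.39 (SE 0.076), and the genes of the proapoptotic proteins BIM (BCL2L11, 0.42, SE 0.11), BAX (0.41, SE 0.12) and NOXA (PMAIP1, 0.35, SE 0.11) rose in the authors' deposited table. The p53 target list had 2 genes that rose, BAX and AEN (0.27, SE 0.079), and 1 that fell, RPS27L, by 0.43 (SE 0.088), among 22 (adjusted p = 0.555), with 2 and 2 adjusted over the list alone. CDKN1A was at -0.42 at a mean level of 74.8 and did not pass.

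Antigen presentation genes of class I rose in 1 of 17 cases, HLA-C at 0.29 (SE 0.062), and those of class II in 2 of 16 cases, HLA-DMA at 0.47 (SE 0.071) and HLA-DQA1 at 0.25 (SE 0.085), with 0 that fell in either list (adjusted p = 0.337 and 0.265, cameraPR). The same counts held adjusted over each list alone. Centred on the summed level without the mitochondrially encoded genes, the calls of HLA-DQA1 (adjusted p = 0.068), ACLY (0.0599), U2AF2 (0.0645), PMVK (0.074) and ICAM3 (0.0775) ended, those of PMVK (0.0508) and ICAM3 (0.0511) also with these genes in the sum. In glycolysis and hypoxia 1 of 23 genes rose, ALDOC, 1.65-fold, and 3 fell, ENO1 by 0.46 (SE 0.073), PFKFB3 by 0.43 (SE 0.14) and PFKL by 0.28 (SE 0.090) (adjusted p = 0.611), also over the list alone, with a median of 0.085, a mean of -0.0012 and a test that pointed to higher values. Fatty acid genes rose in 3 of 13 cases, SCD at 0.31 (SE 0.059), FADS2 at 0.40 (SE 0.12) and ACLY at 0.22 (SE 0.074) (adjusted p = 0.472), and over the list alone 3 rose and 3 fell. Cholesterol genes rose in 1 of 23 cases, PMVK at 0.25 (SE 0.086), and 0 passed over the list alone (adjusted p = 0.784, median -0.021, with a mean of 0.0061 and a test toward higher values). Splicing factor genes rose in 2 of 32 cases, PTBP2 at 0.48 (SE 0.14) and U2AF2 at 0.25 (SE 0.085), and fell in 1, CLK1, by 0.38 (SE 0.13) (adjusted p = 0.337), with the same counts over the list alone. Cytosolic ribosomal protein genes had 1 that rose, RPS19 at 0.20 (SE 0.062), and 1 that fell, RPS15, by 0.17 (SE 0.057), of 40 (adjusted p = 0.116), and 1 that rose over the list alone. Heat shock genes had 1 that rose, HSP90AB1 at 0.22 (SE 0.059), and 1 that fell, HSPH1, by 0.38 (SE 0.065), of 16 (adjusted p = 0.366), and 2 and 1 over the list alone. In trafficking and adhesion ITGA4 fell by 0.31 (SE 0.083) and ICAM3 rose by 0.23 (SE 0.078) among 8 genes (adjusted p = 0.561), and over the list alone 3 rose and 4 fell. Of 30 genes of homologous recombination and mismatch repair and of 11 replication-dependent histone genes, 0 passed in the authors' deposited table or over the list alone (adjusted p = 0.561 for each list). At an unadjusted p under 0.05 there were 0 positive and 5 negative repair genes, and 1 positive and 0 negative histone genes.

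Markers of other cell types were mostly not listed. Of the markers of T and NK cells, 5 of 21 were measured, of which CD247 at 0.28 (SE 0.082) and TRAC at 0.50 (SE 0.16) rose and 0 fell, also over the list alone (adjusted p = 0.337, cameraPR). CD3G had a mean level of 4105 normalized counts in the authors' deposited table and a log2 fold change of -0.16 (SE 0.076), which did not pass. The myeloid list had 1 of 20 members measured, SPI1 at 0.25 (SE 0.12), which did not pass over all genes and passed over the list alone, where it is the only member. The list of fibroblast and epithelial genes had 3 of 18 measured, with DCN, which encodes decorin, falling by 0.54 (SE 0.067) at a mean level of 5347 and TAGLN rising by 0.49 (SE 0.16) at 66.4, also over the list alone. Of 29 cancer-testis genes 1 was measured, MAGEA1 at 0.07, and of the erythroid and megakaryocyte list 0 of 20 were. The lists with fewer than 5 measured genes were not tested.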

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

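No paired analysis was possible because the deposited table has no values per library, and for the same reason the replicate block, other tools and normalizations, pseudocounts, a looser filter, an estimated correlation, leaving out libraries and counting how often other splits of the 6 libraries give as many genes were not run. The settings that centre on the summed level, undo the shrinkage or use ranks were chosen after seeing the data. With an adjusted p under 0.01, 603 genes were called (282 positive, 321 negative), with a log2 change of at least 1 the count was 14 (5 and 9), and with that minimum after undoing the shrinkage it was 87 (40 and 47), in each case fewer by construction. A threshold of 0.1, a minimum level of 50 and centring on the summed level kept the count of 1043 within 1.5 times. A minimum level of 50 shared 1002 of its 1056 calls with the 1043, and centring without the mitochondrially encoded genes, a shift of 0.022 on the log2 scale, shared 957 of its 1081 calls and moved the positive share from 48.4% to 38.8%. SETD2, at -0.24, passed only at the threshold of 0.1. Of the 7 shifted lists, 6 remained with a minimum level of 50 (all but MYC target genes), 3 with a preset correlation of 0.05 (G2/M, mitochondrially encoded and pan-B cell genes), 3 without each list's strongest member (G2/M, mitochondrially encoded and MYC target genes), 2 with ranks (G2/M and mitochondrially encoded genes) and 1 with unshrunken fold changes in place of the statistic (G2/M genes), and the cause was not tested. The adjusted p of the G2/M list ranged from 1.77e-37 to 1.58e-12 over these alternatives, and that of the mitochondrially encoded list from 4.37e-07 to 0.325. The ranges were 0.00102 to 0.436 for pan-B cell, 0.00405 to 0.551 for germinal centre, 0.00843 to 0.436 for unfolded protein response, 0.00751 to 0.325 for immediate early and 0.0188 to 0.632 for MYC target genes. Of the 102 genes other than SETD2 that the naming rule gives, all kept their call with a minimum level of 50, 81 with an adjusted p under 0.01, 100 when centred on the summed level and 97 when the mitochondrially encoded genes were left out of that sum, where HLA-DQA1, ACLY, U2AF2, PMVK and ICAM3 did not pass. The T and NK cell list gave no value without its strongest member, since fewer than 5 genes were left. Depth limits the low genes most: near 50 normalized counts the SE before shrinkage is about as large as the prior's own spread, so that calls there need large changes.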

Other observations

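The tests of proliferation, mitochondrial yield, heavy strand position, the general rise of non-coding transcripts and the genes overlapped by rising transcripts were chosen after the values they measure had been seen. Single genes outside the fixed lists changed as well. Those in this paragraph were chosen after their values were seen, and no set of them was tested. In the authors' deposited table ZWINT, a kinetochore protein gene, fell by 0.87 on the log2 scale (SE 0.090), FBXO5, which encodes the anaphase-promoting complex inhibitor EMI1, by 0.84 (SE 0.13), and PIF1, a DNA helicase gene, by 0.90 (SE 0.13). IKZF3, which encodes the lymphoid transcription factor Aiolos, rose by 0.54 (SE 0.063, adjusted p = 7.01e-15), and the immunoglobulin kappa constant region gene IGKC rose by 0.36 (SE 0.053, adjusted p = 3.48e-09) at a mean level of 21692 normalized counts.

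The first pattern is the fall of G2/M genes. Mean level and GC content of the 3' end are argued against as the cause. The list's median of -0.43 lay below all of 10000 random lists matched on mean level and on the GC content of the last 500 bases. The middle 95% of these lists ran from -0.072 to 0.061. They treat genes as independent, which they are not. GC content was taken from the longest annotated transcript of each gene and matched in bins. A general loss of proliferating cells would lower S phase genes as well, and the medians of the G1/S and G2/M lists differed by 0.49, with a G1/S median of 0.060 (bootstrap 95% interval -0.0095 to 0.089). What stays open, untested, is a shorter or less frequent G2/M phase, lower transcription or stability of these messages, and a difference in culture density at harvest, which a table without libraries cannot separate from the treatment.

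A second pattern is the fall of 6 of the 15 mitochondrially encoded genes. A lower yield of all mitochondrial RNA as the only cause requires a common change. The 15 genes were not alike (Cochran's Q on the deposited SEs against a chi-square distribution, p = 2.55e-15, pooled log2 fold change -0.22). MT-RNR2 was at -0.03, with a lower 95% bound of -0.18. A partial common fall beside changes of single genes stays open. Over the 14 heavy strand genes the log2 fold change was lower the farther along the chromosome the gene starts (Spearman rho = -0.67, permutation p = 0.0106, adjusted over 2 relations 0.0212, Pearson r = -0.67, permutation p = 0.00929, and r = -0.59 without the 2 genes farthest from the median position), a relation across genes, which are not independent replicates. It rests on the first 4 genes, MT-RNR1 to MT-ND2, since over the other 10 rho was -0.19 (permutation p = 0.606), so that distance from the heavy strand promoters stays open as a cause. The mean level of these genes stays open as a cause, since the relation over the 15 genes was negative and did not pass (rho = -0.46, permutation p = 0.0833).

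The third pattern is the presence of antisense and other non-coding transcripts among the largest rises. A general rise of such transcripts stays open. Among called long non-coding genes 32 were positive and 30 negative, against 463 and 499 coding genes (odds ratio 1.15, Fisher's exact p = 0.603). Long non-coding genes were called less often, at 5.89% against 9.79% of coding genes. These shares were not matched on mean level, on which calling depends. The median of the 1053 long non-coding genes exceeded that of level-matched coding genes by 0.024 (bootstrap 95% interval 0.00096 to 0.045). As the only source of the 17 called rises as a set, reads of the overlapping gene on the other strand are argued against. This holds as far as they follow that gene's overall change. Reads that do not follow it were not tested. The genes overlapped by 17 called rising transcripts were positive in 7 and negative in 10 cases. Their median unshrunken log2 fold change was -0.075 (bootstrap 95% interval -0.28 to 0.11), against a lowest rise of 0.39 among the transcripts. Of the 17 transcripts, 15 rose beyond their partner, CD27-AS1 and GLIPR1-AS1 included. The transcripts were chosen as called rises and their partners were not, which by itself favours such differences. A part of the rise from such reads therefore stays open, also for CD27-AS1 and GLIPR1-AS1, whose partners were positive. For ZFHX2-AS1 and AQP5-AS1 reads of the overlapped gene stay open as the source. Their differences from ZFHX2 and AQP5 had lower 95% bounds of -0.58 and -0.073. COLCA1 and ACTR3-AS1 had no measured coding gene of this kind to compare. Over all 432 overlapping pairs rho was 0.051 (permutation p = 0.286, bootstrap 95% interval -0.045 to 0.148). Run-on from a gene upstream on the same strand also stays open, as long non-coding genes within 50 kb of one had a median higher by 0.032 (permutation p = 0.0501, bootstrap 95% interval -0.0027 to 0.063), and COLCA1 lies 47.2 kb downstream of POU2AF1 (mean level 16849, log2 fold change 0.02).

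Since H3K36 trimethylation covers gene bodies, longer genes might be expected to move more in one direction. Over 9826 coding genes the correlation of log2 fold change with gene span was small (rho = -0.033, permutation p = 0.0011, and -0.030 given the mean level), with medians of -0.003 in the shortest 10% of genes and -0.029 in the longest. Zinc finger genes may share a slight fall. The median of 383 ZNF genes was -0.043, against a middle 95% of -0.038 to 0.0089 over 10000 level-matched random lists. Of the ZNF genes 10 were called lower and 2 higher, which is 3.13% of them against 9.79% of coding genes. These shares were not matched on mean level. With GC content matched as well, the ZNF median stood at percentile 1.05 of the random lists, whose middle 95% began at -0.039. GC content was matched in bins, so a difference within bins may remain, and this margin does not exclude GC content as the source. Both comparisons treat genes as independent replicates, which they are not, so that the small margin does not establish a shared fall.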
